A study of Mus musculus with 16 samples.

How the data were processed

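The labels describe total RNA taken with a Qiagen kit, mRNA enrichment and random-hexamer libraries from an Illumina TruSeq kit. The submitters' processing notes name CASAVA and the mm10 build. The aligner, the counting tool, the annotation and the release of DESeq2 used by the authors are not given in the sources used here. Per the file headers the authors' tables hold, for each gene, a signal value that is the mean over 8 libraries of read counts divided by size factors. The log2 fold change and its standard error were fitted by the authors with DESeq2 for a pair of groups. The authors' Wald score is the log2 fold change divided by that standard error. The authors' p-value is that of the Wald score, two-sided, and their adjusted value is Benjamini-Hochberg after a filter on low means. An adjusted p of exactly 1 in the deposited tables was read as missing, because the smallest adjusted p divided by its p equals the number of genes with any other value. No values per library were analysed here.

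The design, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. A gene was called at the authors' adjusted p under 0.05. The difference of infection effects was tested as CCL28KO minus WT over the root of the summed squared standard errors, two-sided, for 14972 genes with a mean of at least 10 in both infection tables, with Benjamini-Hochberg adjustment. The infection tables share no library. Of 38 lists fixed in advance, 2 served as checks, 1 had no measured member and 35 were tested with limma's cameraPR on the Wald score, two-sided, with a preset correlation of 0.01 and adjustment over the lists of a comparison. A list was tested when at least 3 members had a Wald score and a p-value. Of 810 list entries 757 matched a gene of the tables. A further 6 lists were written after the data were seen.

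In each comparison the text could name Ccl28, the 8 strongest rises and 8 strongest falls among called genes with a mean of at least 50 and an established symbol, up to 4 members of each list that passed, and 10 further genes fixed in advance. Other genes are marked as chosen after their values were seen. Approximate group means were computed from the mean and the fold change. Library sizes were approximated from the smallest steps of the mean, which give the size factor of a library where 1 read was seen in 1 gene. Both paths around the 4 tables gave the same sum of changes, with a median discrepancy of 5.45e-04 and a largest one of 0.00961 log2 units over 12867 genes. Positions and exon lengths came from GENCODE M21 on GRCm38, to which 19842 of 20112 genes matched, 19096 of them by symbol. Rows identical between genes, such as Klk1b26 and Egfbp2, and families with near-identical copies are uncertain.

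Centring by exon length subtracted the median change of each of 50 length bins and was added after the data were seen. The steps were tried on simulated statistics in which genes were changed by 0.5, 1 or 2 log2 units. At 1 log2 unit the test recovered between 77.6% and 91.0% of changed genes in the pairwise tables and 70.1% for the difference. At 0.5 units the recovery was 49.3% to 71.6% and 25.4%. cameraPR passed 0 of 700 unchanged lists and 19 of 20 shifted lists, and centring took a planted length trend from a Spearman of 0.560 to 0.00422. The simulated genes were independent, so the 0 of 700 does not measure false passes among correlated list members. Their scores also spread less than the authors' Wald score for infection in WT, which had a robust SD of 1.78. A planted run of calls gave 55 pairs within 1 Mb against at most 33 in random sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.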

Results

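RNA was sequenced from whole tongues of wild-type mice (WT) and of mice lacking the chemokine CCL28 (CCL28KO), 1 day after oral inoculation with the yeast Candida albicans or a sham inoculum. CCL28 is made by mucosal epithelia, attracts cells that carry its receptors CCR10 and CCR3, and can kill microbes directly. The 16 samples formed 4 groups of 4: WT sham, WT infected, CCL28KO sham and CCL28KO infected. Expression values came as 4 tables of pairwise comparisons computed by the authors, covering infection in WT, infection in CCL28KO, genotype in sham tongues and genotype in infected tongues. Each table held between 19589 and 19682 genes, and its mean normalised counts summed to between 19.9 and 21.7 M. Size factors recovered from those means placed each library at roughly 16.8 to 24.2 M counted reads. Changes are log2 fold changes with the standard error of the authors' fit, and a gene was called at an adjusted p under 0.05. The sample labels do not say that replicates were separate animals, so p-values measure only the spread between these samples, which may be technical. Values per library were not analysed, so the number of samples sharing a direction cannot be given.

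Ccl28, on chromosome 13 at 119623819 to 119654359 of the GRCm38 build (plus strand), was the targeted gene. In sham tongues the authors' deposited table put Ccl28 at -3.61 ± 0.68 in CCL28KO against WT (adjusted p = 6.14e-05), which is 0.0819-fold. The mean normalised counts implied by the authors' deposited table were 1.75 for Ccl28 in CCL28KO sham and 21.3 in WT sham. After infection Ccl28 was again lower, at -4.11 ± 0.77 (adjusted p = 5.95e-05), with 1.80 against 31.1 implied counts in the authors' deposited table. Infection in WT left Ccl28 uncalled at 0.65 ± 0.43 (adjusted p = 0.352) in the authors' deposited table. Neither receptor gene was called in infected WT tongues, where the authors' deposited table gave Ccr10 (-0.42) and Ccr3 (0.81), both without an adjusted p.

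Infection in WT tongues addressed which genes respond to the yeast within 1 day when CCL28 is present. Of 14716 genes with an adjusted p, 844 rose and 1214 fell, and 4035 genes had an unadjusted p under 0.05. Most changes were small, with a median log2 change of 0.29 among the genes that rose and -0.30 among those that fell. A change of at least 1 log2 unit was reached by 75 genes that rose and 12 that fell. The strongest rise among genes with a mean of at least 50 was that of Saa3, an acute-phase protein made at inflamed epithelia, at 6.68 ± 1.22 or 103-fold (adjusted p = 3.13e-06) in the authors' deposited table. The cornified-envelope genes Sprr2f (5.26 ± 0.83) and Sprr2d (5.04 ± 1.30) and the chitinase-like Chil1 (4.33 ± 0.63) followed in the authors' deposited table, although reads of Sprr2 copies are hard to tell apart. The authors' deposited table also placed the calprotectin subunits S100a9 (3.95 ± 0.58) and S100a8 (3.51 ± 0.47) and the cytokine Il1b (3.71 ± 0.64) among the strongest rises. The strongest falls at such means in the authors' deposited table were Fam166a (-1.24 ± 0.15), the nuclear receptor Nr4a3 (-1.14 ± 0.22) and the splicing-related Ccdc84 (-1.09 ± 0.17).

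Neutrophil genes rose as a group in infected WT tongues (23 genes, median 2.06, adjusted p = 1.03e-11, 10 up and 1 down, or 13 and 1 adjusted over the list alone). In such brackets the median is the log2 change of the measured members, and the adjusted p is from limma's cameraPR with a preset correlation of 0.01. The counts called up and down are over all genes, then adjusted over the list alone. No correlation could be estimated without values per library. Clec4e, a receptor for fungal glycolipids, was at 4.90 ± 0.88 in the authors' deposited table, and the list's only fall was Asprv1 (-0.39 ± 0.06). Chemokines and growth factors that attract neutrophils had the highest median of the lists fixed in advance (10 genes, median 3.68, adjusted p = 6.14e-11, 5 up and 0 down, or 9 and 0 adjusted over the list alone). The 5 that rose were Cxcl1 (4.04), Il1b (3.71), Cxcl5 (1.49), Cxcl2 (4.38) and the platelet chemokine Ppbp (1.13) in the authors' deposited table. Genes of the IL-17 axis and its epithelial targets rose too (27 genes, median 2.18, adjusted p = 3.98e-16, 9 up and 1 down, or 18 and 1 adjusted over the list alone). Mmp3, a matrix-degrading protease, rose by 2.27 ± 0.19 or 4.82-fold in the authors' deposited table, as did Steap4 (0.80 ± 0.12) and the IL-17 signal amplifier Nfkbiz (1.53 ± 0.27). The receptor subunit gene Il17rc was the list's only fall, at -0.26 ± 0.08 in the authors' deposited table. The cytokine genes themselves were near the detection floor in WT, and the authors' deposited table gave Il17a (5.11 ± 1.41), Il17f (4.61 ± 1.23) and Il22 (4.32 ± 1.65) without adjusted p-values. Adjusted over all genes with a p, Il17a (adjusted p = 0.00629) and Il17f (adjusted p = 0.00418) were called higher in WT, and Il22 was not (adjusted p = 0.0773).

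Other lists of innate defence genes moved in the same direction, although they shared members with each other and with the lists above. S100a8 and S100a9 counted as neutrophil and antimicrobial genes, Clec4e as neutrophil and fungal-sensing, and Saa3 as antimicrobial and acute-phase. Monocyte and macrophage genes rose (20 genes, median 0.48, adjusted p = 4.48e-06, 6 up and 0 down, or 9 and 0 adjusted over the list alone). Among them were Mrc1 (0.64), Cd14 (0.91) and Fcgr1 (1.49) in the authors' deposited table. Monocyte-attracting chemokines rose as well (14 genes, median 0.76, adjusted p = 4.48e-06, 4 up and 0 down, or 6 and 0 adjusted over the list alone). The calls were Ccl9 (0.79), Ccl6 (0.72), Ccl7 (1.87) and Ccl2 (1.28) in the authors' deposited table. Complement and acute-phase genes rose broadly (23 genes, median 0.56, adjusted p = 2.66e-12, 10 up and 0 down, or 13 and 0 adjusted over the list alone). The protease inhibitor Serpina3n (1.54 ± 0.17) and the complement gene C3 (0.54 ± 0.08) had the smallest adjusted p among them in the authors' deposited table. Fungal-sensing genes were higher as a list (22 genes, median 0.18, adjusted p = 3.99e-05, 8 up and 1 down, or 9 and 1 adjusted over the list alone). The transcription factor Fos (-0.56 ± 0.15) fell in the authors' deposited table. The IL-1 family and inflammasome list was also higher (14 genes, median 0.26, adjusted p = 2.70e-04, 7 up and 1 down, or 9 and 1 adjusted over the list alone). Its adaptor gene Pycard (-0.34 ± 0.08) fell in the authors' deposited table. Antimicrobial peptides and proteins passed at the preset correlation of 0.01 (29 genes, median 0.23, adjusted p = 0.00691, or adjusted p = 0.197 at preset 0.1, 6 up and 1 down, or 6 and 1 adjusted over the list alone). The secreted protease inhibitor Slpi (-0.46 ± 0.08) fell in the authors' deposited table. The type I interferon list passed narrowly (29 genes, median 0.16, adjusted p = 0.0482, or adjusted p = 0.402 at preset 0.1, 2 up and 0 down, or 1 and 0 adjusted over the list alone). The members called were Ifih1 (0.45) and Zbp1 (1.16) in the authors' deposited table. Defb3, an epithelial beta-defensin, was not called at 0.25 ± 0.20 (adjusted p = 0.466) in the authors' deposited table.

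Vessel and matrix genes responded alongside. The endothelial list rose (17 genes, median 0.17, adjusted p = 1.94e-04, 4 up and 0 down, or 4 and 0 adjusted over the list alone). Its calls were the leukocyte-adhesion genes Selp (2.27), Sele (1.40) and Icam1 (0.43) and the chemokine scavenger Ackr1 (0.69) in the authors' deposited table. Fibroblast and matrix genes rose slightly (23 genes, median 0.08, adjusted p = 0.00115, or adjusted p = 0.0835 at preset 0.1, 3 up and 0 down, or 3 and 0 adjusted over the list alone). Besides Mmp3 the calls were Timp1 (1.94) and Pdgfra (0.41) in the authors' deposited table. Hypoxia and glycolysis genes rose (16 genes, median 0.05, adjusted p = 0.00640, or adjusted p = 0.110 at preset 0.1, 5 up and 0 down, or 5 and 1 adjusted over the list alone). They were Pfkfb3 (0.78), Hif1a (0.37), Slc2a1 (0.40), Ero1l (0.29) and Egln3 (0.28) in the authors' deposited table.

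Epithelial lists gave mixed results in infected WT tongues. The differentiation list of the tongue epithelium was lower (33 genes, median -0.10, adjusted p = 0.00505, or adjusted p = 0.197 at preset 0.1, 2 up and 6 down, or 2 and 6 adjusted over the list alone). After centring by exon length its median was -0.04 (standard error 0.05 across members, 0.06 before) and its adjusted p 0.0974, with the list nearer 0. Lor, a cornified-envelope protein, fell to 0.594-fold (-0.75 ± 0.08), and Krt78 (-0.38) and Krt5 (-0.39) fell while the adhesion gene Dsg3 (0.53) and the epithelial factor Elf3 (0.51) rose in the authors' deposited table. Stress keratins and barrier-alarm genes went both ways (37 genes, median 0.17, adjusted p = 0.182, 9 up and 7 down, or 11 and 7 adjusted over the list alone), so the list did not pass, although its adjusted p was 1.05e-04 after centring by exon length, at a median of 0.26 (standard error 0.31 across members before and after). Sprr2e rose by 6.81, whereas the envelope genes Lce3f (-0.59) and Lce3c (-0.51) and the wound keratin Krt16 (-0.25) fell in the authors' deposited table. Krt13, the dominant keratin of the oral lining, was at -0.10 ± 0.07 and uncalled in the authors' deposited table. Immediate-early and heat-shock genes fell (20 genes, median -0.15, adjusted p = 2.79e-08, 0 up and 7 down, or 0 and 8 adjusted over the list alone). The smallest adjusted p were those of Hspa1a (-0.65), Nr4a1 (-0.88), Atf3 (-0.94) and Fosb (-0.99) in the authors' deposited table.

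Nuclear-encoded genes of oxidative phosphorylation fell as a list (29 genes, median -0.18, adjusted p = 1.17e-23, 0 up and 19 down, or 0 and 22 adjusted over the list alone). Ndufa2, a complex I subunit, fell to 0.558-fold (-0.84 ± 0.10), with Cox5b (-0.53), Ndufa1 (-0.67) and Cox8b (-0.53) in the authors' deposited table. Fast skeletal muscle genes did not move as a list (25 genes, median -0.01, adjusted p = 0.0947, 1 up and 5 down, or 2 and 6 adjusted over the list alone). The titin gene Ttn rose by 0.32 while Tnnc2 (-0.47), Tnni2 (-0.28), Mylpf (-0.24), Eno3 (-0.23) and Mb (-0.18) fell in the authors' deposited table. Of the mucosal chemokine list (13 genes, median 0.14, adjusted p = 0.853, 0 up and 1 down, or 1 and 1 adjusted over the list alone), the eosinophil attractant Ccl24 fell by -0.68 in the authors' deposited table. Il17rc, Krt16, Elf3, Ppbp, Egln3, Eno3 and Mb were singled out after their values were seen. WT changes rose with exon length (Spearman 0.363 over 12966 genes, which are not independent replicates), from a median of -0.17 for 410 genes with exons under 1000 bases to 0.10 for 2317 genes over 8000 bases. After centring by exon length 486 genes rose and 969 fell. Calls that ended are given as the log2 change in the authors' deposited table, then centred, with the standard error of both: Ifih1 (0.45 to 0.37 ± 0.14), Zbp1 (1.16 to 1.15 ± 0.42), Pdgfra (0.41 to 0.31 ± 0.13), Ccl24 (-0.68 to -0.60 ± 0.23), Ttn (0.32 to 0.16 ± 0.09), Mylpf (-0.24 to -0.12 ± 0.07), Il17rc (-0.26 to -0.22 ± 0.08), Krt16 (-0.25 to -0.16 ± 0.08), Eno3 (-0.23 to -0.13 ± 0.07) and Mb (-0.18 to -0.09 ± 0.07). All moved toward 0, but Zbp1 hardly did and its call ended because the largest p called went from 0.00698 to 0.00498. Lists that still passed after centring but moved by over 1.5 times were the antimicrobial (median 0.23 to 0.34, standard error 0.30 for both), fibroblast (0.08 to 0.05, standard errors 0.13 and 0.14) and hypoxia lists (0.05 to 0.00579, standard error 0.07 for both). Adjusted over all genes, Zbp1 (adjusted p = 0.0587) and Mb (adjusted p = 0.0642) were not called either.

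**Figure D1:**
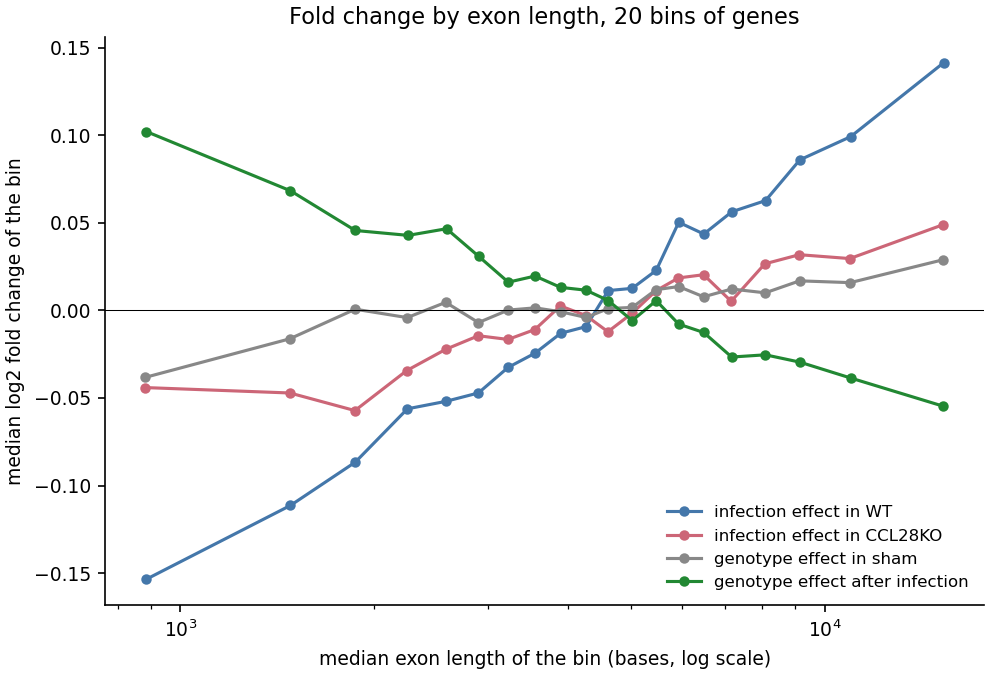
Median log2 fold change (y axis) of 20 bins of genes ordered by exon length in bases (x axis, log scale), 1 line per pairwise comparison. The WT infection line climbs with length, and the line for genotype in infected tongues descends.

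Infection in CCL28KO tongues asked for the same response without the chemokine. Of 16546 genes with an adjusted p, 318 rose and 104 fell, and 1967 had an unadjusted p under 0.05. A rise of at least 1 log2 unit was reached by 192 genes and such a fall by 13. The median rise was 1.29 and the median fall -0.61. The standard errors were larger than in WT, with a median of 0.130 against 0.0934 for genes at a mean of 50 or more. Small changes could thus less often be called, so medians of called genes cannot be compared between genotypes. The 844 genes called higher in WT had a median of 0.29 in WT and 0.15 in CCL28KO. The 1214 called lower in WT had medians of -0.30 and -0.11, and choosing genes by their WT values favours WT. Among genes with a mean of at least 50, Saa3 led at 11.44 ± 1.56 (adjusted p = 8.32e-10), followed in the authors' deposited table by Irg1 (8.29 ± 1.88), which makes the antimicrobial metabolite itaconate, and the envelope gene Sprr2e (7.92 ± 0.91). The epithelial cytokine Il19 (7.72 ± 1.39), Chil1 (7.44 ± 0.75) and Ccl20 (7.04 ± 1.48), which attracts IL-17-producing cells, came next in the authors' deposited table. The strongest falls at such means in the authors' deposited table were the immediate-early gene Fosb (-1.73 ± 0.17), the microtubule gene Tppp3 (-1.09 ± 0.20) and the germ-cell transcription factor Mybl1 (-1.05 ± 0.22).

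The IL-17 axis had the smallest adjusted p of the lists fixed in advance in CCL28KO (28 genes, median 4.05, adjusted p = 5.48e-44, 20 up and 0 down, or 23 and 0 adjusted over the list alone). Il17f rose by 8.45 ± 1.45 (adjusted p = 4.93e-06), Il17a by 7.88 ± 1.70 (adjusted p = 6.65e-04) and Il22 by 5.45 ± 1.68 (adjusted p = 0.0483) in the authors' deposited table, the last with adjusted p = 0.0570 over all genes. Il17f and Il22 were near the detection floor in sham tongues of both genotypes. They had no adjusted p there, where genes with a p lacked one only at means up to 1.28. Their targets Nfkbiz (2.55), Cxcl1 (6.47) and Zc3h12a (2.53), the last a nuclease that limits cytokine messages, rose in the authors' deposited table. Defb3 was called here and rose 3.99-fold (adjusted p = 0.00378) in the authors' deposited table. Neutrophil genes rose (23 genes, median 3.43, adjusted p = 3.57e-25, 12 up and 0 down, or 18 and 0 adjusted over the list alone). Smallest in adjusted p in the authors' deposited table were S100a8 (4.65), the cystatin Stfa2l1 (6.78) and the amplifying receptor Trem1 (4.62), and S100a9 was at 4.31. Neutrophil-attracting chemokines rose (11 genes, median 5.18, adjusted p = 2.97e-23, 8 up and 0 down, or 10 and 0 adjusted over the list alone). The smallest adjusted p were those of Cxcl1, Il1b (5.18), Cxcl3 (6.04) and Cxcl2 (6.36) in the authors' deposited table. Antimicrobial genes rose (27 genes, median 0.29, adjusted p = 1.85e-06, 7 up and 1 down, or 8 and 1 adjusted over the list alone). The cathelicidin gene Camp (-2.71 ± 0.64) was lower in the authors' deposited table. This fall was from a raised sham level, because Camp was called higher in CCL28KO sham than in WT sham tongues. In infected tongues Camp stood at -0.11 in CCL28KO against WT, without an adjusted p, in the authors' deposited table.

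Interferon-gamma-stimulated genes rose in CCL28KO (23 genes, median 0.70, adjusted p = 7.97e-12, 5 up and 0 down, or 9 and 0 adjusted over the list alone). The checkpoint ligand Cd274 (1.24), the defence GTPases Gbp5 (1.24), Irgm2 (0.94) and Gbp2 (0.77) and the transcription factor Irf1 (0.84) were the calls in the authors' deposited table. Complement and acute-phase genes rose (23 genes, median 1.24, adjusted p = 2.65e-18, 7 up and 0 down, or 16 and 0 adjusted over the list alone). Among them were Saa1 (4.37) and the cytokine-signal inhibitor Socs3 (2.05) in the authors' deposited table. IL-1 family and inflammasome genes rose (14 genes, median 0.50, adjusted p = 1.36e-07, 4 up and 0 down, or 7 and 0 adjusted over the list alone). The calls besides Il1b were Nlrp3, Il1a and Casp4. Fungal-sensing genes rose (22 genes, median 0.24, adjusted p = 1.34e-08, 6 up and 0 down, or 9 and 1 adjusted over the list alone). They included the dectin gene Clec4n (3.71) and Tlr2 (1.43) in the authors' deposited table. Monocyte chemokines rose (14 genes, median 0.64, adjusted p = 7.51e-08, 3 up and 0 down, or 8 and 0 adjusted over the list alone) through Ccl7, Ccl12 and Ccl2. Monocyte and macrophage genes did so (20 genes, median 0.27, adjusted p = 4.55e-04, 3 up and 0 down, or 5 and 1 adjusted over the list alone), with Cd14 and Plac8 among the calls. The glucocorticoid-response list rose (16 genes, median 0.52, adjusted p = 1.65e-06, 2 up and 0 down, or 3 and 0 adjusted over the list alone). Its calls were the inhibitor gene Nfkbia and the iron-binding Lcn2. Endothelial genes rose (17 genes, median 0.28, adjusted p = 2.90e-10, 5 up and 0 down, or 5 and 0 adjusted over the list alone). The calls were Sele (3.63), Icam1 (1.60), Selp (3.27), Ackr1 (1.25) and Vcam1 (0.83) in the authors' deposited table. Gbp2 and Vcam1 were singled out after their values were seen. Gbp2 had adjusted p = 0.0587 over all genes, and Vcam1 adjusted p = 0.0519 after centring by exon length, at 0.79 ± 0.25.

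Stress keratins and barrier-alarm genes rose as a list in CCL28KO (37 genes, median 0.30, adjusted p = 1.51e-15, 8 up and 0 down, or 13 and 0 adjusted over the list alone). The tongue differentiation list was lower (33 genes, median -0.18, adjusted p = 7.64e-04, or adjusted p = 0.0891 at preset 0.1, 2 up and 0 down, or 2 and 4 adjusted over the list alone). Its calls, Dsg3 (1.09) and Elf3, nevertheless rose in the authors' deposited table. Salivary genes rose (25 genes, median 0.42, adjusted p = 1.89e-04, 1 up and 0 down, or 2 and 0 adjusted over the list alone). The peroxidase Lpo (2.13) was their single call in the authors' deposited table. Cell-cycle genes fell (28 genes, median -0.59, adjusted p = 5.75e-12, 0 up and 3 down, or 0 and 13 adjusted over the list alone). The mitotic kinase Aurkb (-0.76), the transcription factor Foxm1 (-0.61) and the spindle gene Nusap1 (-0.90) were called lower in the authors' deposited table. Erythrocyte genes fell (10 genes, median -0.54, adjusted p = 1.03e-05, 0 up and 2 down, or 0 and 2 adjusted over the list alone). The anion exchanger Slc4a1 (-1.35) was among the calls in the authors' deposited table. B-cell and plasma-cell genes were lower as a list without a single call (13 genes, median -0.85, adjusted p = 0.0151, or adjusted p = 0.104 at preset 0.1, 0 up and 0 down, or 0 and 0 adjusted over the list alone). In the same comparison 6 granule genes of immature neutrophils had a median of -2.72 and 5 bone genes one of -3.01, both lists written after the data were seen. In sham tongues these lists were higher in CCL28KO, at medians of 3.99 and 5.27, as was Slc4a1 (2.37 in the authors' deposited table). Oxidative phosphorylation did not pass (29 genes, median -0.03, adjusted p = 0.266, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Fast muscle genes did not pass either (25 genes, median 0.00, adjusted p = 0.859, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Dendritic-cell, type I interferon, muscle-stress, circadian and hypoxia lists passed upward but not at a preset correlation of 0.1, where their adjusted p lay between 0.0715 and 0.204. Their calls were Ccl17, Gadd45a, Runx1, Mstn and Pfkfb3.

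**Figure D2:**
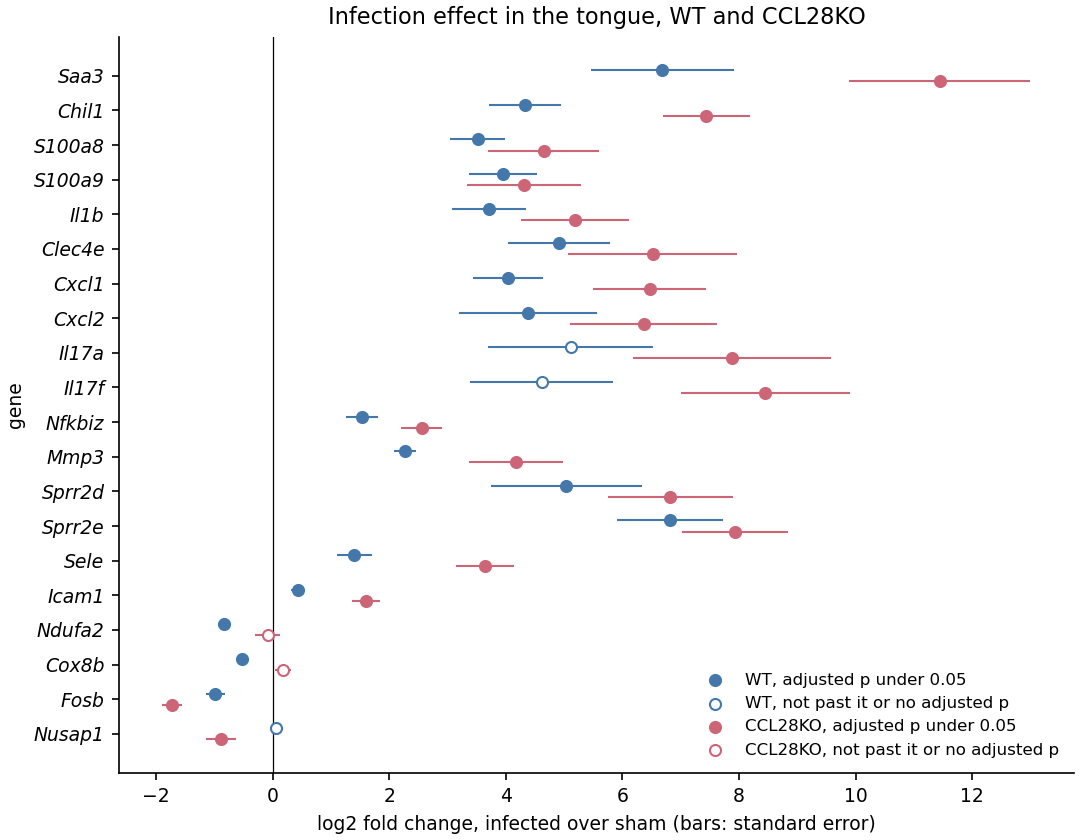
Log2 fold change, infected over sham (x axis), of 20 genes (y axis) in WT and CCL28KO tongues, with bars for the standard error of the authors' fit and filled points for an adjusted p under 0.05. The inflammatory genes lie to the right of 0 in both genotypes, and the oxidative phosphorylation genes Ndufa2 and Cox8b lie to the left in WT.

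Both genotypes shared a direction of response. Across 14972 genes, which are not independent replicates, the infection effects correlated at a Pearson r of 0.580 and a Spearman rho of 0.352. Of the genes tested in both, 159 rose in both genotypes where 15.8 would be shared by independent lists, 45 fell in both against 8.02, and 0 were called in opposite directions. A Wald test of the difference between the infection effects, CCL28KO minus WT, called 8 genes higher and 0 lower at an adjusted p under 0.05. By this test 1250 genes had an unadjusted p under 0.05. The adhesion gene Icam1 differed by 1.17 ± 0.27 (adjusted p = 0.0363), with 0.43 in WT and 1.60 in CCL28KO in the authors' deposited tables. The ATP synthase subunit Atp5k (1.05 ± 0.23), the stress gene Ier3 (0.99 ± 0.22) and the cytochrome oxidase gene Cox8b (0.70 ± 0.16) differed too. So did the ribosomal Rps29 (0.84 ± 0.17), Rpl38 (0.74 ± 0.14) and Rps28 (0.70 ± 0.15) and the envelope gene Lce3a (0.67 ± 0.16). Most of these differences stood on falls in WT, where the authors' deposited table gave Rps29 (-0.66), Rpl38 (-0.46), Rps28 (-0.54), Atp5k (-0.81) and Lce3a (-0.62). None of the 8 kept an adjusted p under 0.05 after centring by exon length, with 0 genes called in either direction, or with the statistic scaled to its robust SD. Centring took the differences to Icam1 (1.17 to 1.15 ± 0.27), Atp5k (1.05 to 0.84 ± 0.23), Ier3 (0.99 to 0.88 ± 0.22), Rps29 (0.84 to 0.72 ± 0.17), Rpl38 (0.74 to 0.53 ± 0.14), Cox8b (0.70 to 0.50 ± 0.16), Rps28 (0.70 to 0.66 ± 0.15) and Lce3a (0.67 to 0.46 ± 0.16), before and after. All stayed above 0 but moved toward it at the same standard errors, and Rps28 lost its call because the p of the others rose.

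As lists, 10 were higher and 2 lower in their difference between genotypes. Among these, IL-17 axis genes had the largest median difference (17 genes, median 1.63, adjusted p = 3.75e-07, 0 up and 0 down, or 3 and 0 adjusted over the list alone). Defb3 differed by 1.75 ± 0.52 and was uncalled (adjusted p = 0.211). Interferon-gamma-stimulated genes also had larger infection effects in CCL28KO (22 genes, median 0.50, adjusted p = 1.01e-06, 0 up and 0 down, or 3 and 0 adjusted over the list alone). So did complement and acute-phase genes (18 genes, median 0.50, adjusted p = 1.97e-04, 0 up and 0 down, or 2 and 0 adjusted over the list alone) and, to a lesser size, stress keratins (34 genes, median 0.30, adjusted p = 1.01e-06, 0 up and 0 down, or 4 and 0 adjusted over the list alone). The same direction held for the neutrophil list (18 genes, median 0.75, adjusted p = 8.62e-04, or adjusted p = 0.0543 at preset 0.1, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Antimicrobial genes followed it (23 genes, median 0.28, adjusted p = 0.00565, or adjusted p = 0.156 at preset 0.1, 0 up and 0 down, or 2 and 0 adjusted over the list alone), although their adjusted p was 0.148 after centring by exon length, at a median of 0.16 (standard error 0.26 across members before and after). Glucocorticoid-response genes were likewise higher in the difference (16 genes, median 0.51, adjusted p = 1.69e-04, 0 up and 0 down, or 1 and 0 adjusted over the list alone). Immediate-early genes were higher with Ier3 called (20 genes, median 0.22, adjusted p = 6.97e-04, or adjusted p = 0.0543 at preset 0.1, 1 up and 0 down, or 3 and 1 adjusted over the list alone). Endothelial genes passed with Icam1 as their call (17 genes, median 0.11, adjusted p = 0.00878, or adjusted p = 0.151 at preset 0.1, 1 up and 0 down, or 2 and 0 adjusted over the list alone). Oxidative phosphorylation genes differed upward with Cox8b called (29 genes, median 0.15, adjusted p = 2.05e-08, 1 up and 0 down, or 4 and 0 adjusted over the list alone). Cell-cycle genes differed downward (28 genes, median -0.56, adjusted p = 1.58e-10, 0 up and 0 down, or 0 and 6 adjusted over the list alone). The CCL28KO sham tongues in this difference had higher granule, bone, erythrocyte and cell-cycle genes than WT sham tongues (medians 3.99, 5.27, 0.29 and 0.15). The 6 granule and 5 bone genes were picked after the data were seen. Another 19 bone genes, not looked at before, had a median of 0.09 in sham tongues. Mast-cell, eosinophil and type 2 genes differed downward as well (13 genes, median -0.39, adjusted p = 8.62e-04, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Nusap1 had a difference of -0.96 ± 0.28 (adjusted p = 0.208) and the mast-cell protease Cpa3 one of -0.73 ± 0.26 (adjusted p = 0.382), both uncalled. The neutrophil-attracting chemokines had 6 members with enough signal and did not pass (6 genes, median 2.14, adjusted p = 0.102, 0 up and 0 down, or 1 and 1 adjusted over the list alone).

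**Figure D3:**
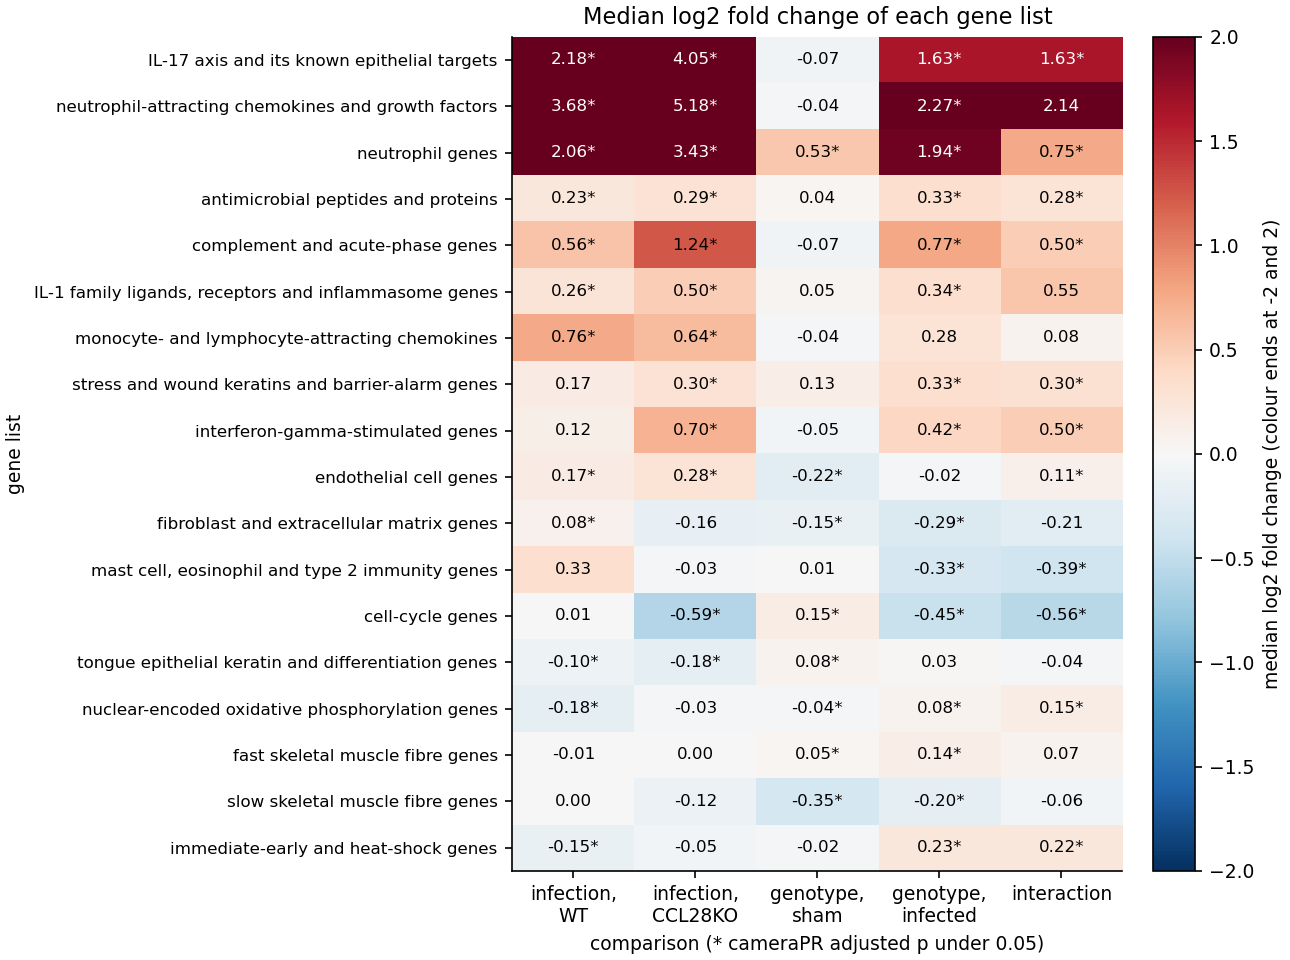
Median log2 fold change of 18 gene lists (y axis) in the 4 pairwise comparisons and the difference of infection effects (x axis), with colour ending at -2 and 2 and an asterisk for a cameraPR adjusted p under 0.05. The IL-17 list stands at 2.18 in WT, 4.05 in CCL28KO and 1.63 for the difference.

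Genotype in sham tongues compared CCL28KO with WT without infection. A difference here need not come from CCL28 loss, because calls lay in runs along chromosomes, as described below. Among 17324 genes with an adjusted p, 64 were higher and 45 lower in CCL28KO, and 896 had an unadjusted p under 0.05. The strongest falls among genes with a mean of at least 50 in the authors' deposited table were Wdr65 (-5.33 ± 0.46), a gene of motile cilia, and Tceanc2 (-3.22 ± 0.16) (adjusted p = 9.18e-88), which left 0.107-fold of the WT level. Erdr1, Fgfbp3 and Kcnn2 followed at -2.04, -1.64 and -1.18 in the authors' deposited table. Of these genes, Wdr65 and Tceanc2 lie in such runs of calls. Ngp, a granule protein of immature neutrophils, was the strongest rise at such means, at 3.42 ± 0.68, ahead of S100a8 (1.75 ± 0.35) and the immediate-early Egr1 (1.10 ± 0.14) in the authors' deposited table. Neutrophil genes were higher (23 genes, median 0.53, adjusted p = 3.71e-05, 3 up and 0 down, or 6 and 0 adjusted over the list alone). The calls were S100a8, Retnlg (2.42) and Cd177 (2.41) in the authors' deposited table. Antimicrobial genes missed the threshold as a list (28 genes, median 0.04, adjusted p = 0.0526, 3 up and 0 down, or 5 and 1 adjusted over the list alone), with an adjusted p of 0.01003 after centring by exon length. S100a8, Ngp and Camp (2.82) were its calls in the authors' deposited table. The granule genes Elane (5.19), Mpo (4.34) and Prtn3 (4.40) and the bone-matrix genes Ibsp (6.07), Mepe (5.72) and Bglap (3.48) were also called higher in the authors' deposited table. These 6 were chosen after their values were seen.

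Muscle fibre lists moved apart in CCL28KO sham tongues. Fast muscle genes were higher (25 genes, median 0.05, adjusted p = 0.00185, or adjusted p = 0.133 at preset 0.1, 3 up and 0 down, or 4 and 0 adjusted over the list alone). Slow muscle genes were lower (10 genes, median -0.35, adjusted p = 3.71e-05, 0 up and 1 down, or 0 and 4 adjusted over the list alone). The calls were Pvalb (0.56), Mybpc2 (0.39) and Actn3 (0.99) on the fast side and Myoz2 (-0.46) on the slow side in the authors' deposited table. Erythrocyte genes were higher (10 genes, median 0.29, adjusted p = 4.47e-05, 1 up and 0 down, or 2 and 0 adjusted over the list alone). Of these, Slc4a1 (2.37 ± 0.43) was called in the authors' deposited table. Marrow precursor genes (18 genes, median 1.02, 0 called) and granule genes of immature neutrophils (6 genes, median 3.99) were higher in the same comparison. Both lists were written after the data were seen. Adipocyte genes were higher (16 genes, median 0.18, adjusted p = 0.00214, or adjusted p = 0.0879 at preset 0.1, 1 up and 0 down, or 1 and 0 adjusted over the list alone). The lipase Lpl (0.58 ± 0.08) was called in the authors' deposited table. Endothelial genes were lower without a call (17 genes, median -0.22, adjusted p = 3.71e-05, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Fibroblast genes were lower on the same terms (23 genes, median -0.15, adjusted p = 3.25e-04, or adjusted p = 0.0681 at preset 0.1, 0 up and 0 down, or 0 and 2 adjusted over the list alone). Cell-cycle genes were higher (28 genes, median 0.15, adjusted p = 3.71e-05, 0 up and 0 down, or 0 and 0 adjusted over the list alone). So were the tongue differentiation list (33 genes, median 0.08, adjusted p = 6.05e-05, or adjusted p = 0.0681 at preset 0.1, 0 up and 0 down, or 0 and 0 adjusted over the list alone) and salivary genes (23 genes, median 0.42, adjusted p = 0.00700, or adjusted p = 0.186 at preset 0.1, 0 up and 0 down, or 0 and 0 adjusted over the list alone). Type I interferon genes passed upward, and antigen presentation and oxidative phosphorylation downward, but not at a preset correlation of 0.1, where their adjusted p lay between 0.133 and 0.334. The IL-17 axis did not differ detectably before infection (26 genes, median -0.07, adjusted p = 0.452, 0 up and 0 down, or 0 and 1 adjusted over the list alone). Stress keratins did not pass either (37 genes, median 0.13, adjusted p = 0.202, 0 up and 0 down, or 1 and 0 adjusted over the list alone), with an adjusted p of 0.0491 after centring by exon length.

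Genotype in infected tongues compared both genotypes after the yeast. Among 15446 genes with an adjusted p, 157 were higher and 99 lower in CCL28KO, and 2310 had an unadjusted p under 0.05. Among genes with a mean of at least 50, Alox8, an epidermal lipoxygenase, was 11.3-fold higher at 3.50 ± 0.58 (adjusted p = 1.46e-06), followed by Chil1 (3.23 ± 0.78) and Sprr2b (3.22 ± 0.68) in the authors' deposited table. Wdr65, Tceanc2 and Erdr1 were again the strongest falls at such means, at -6.14, -3.24 and -3.17 in the authors' deposited table. The IL-17 list was higher in CCL28KO (28 genes, median 1.63, adjusted p = 3.22e-12, 4 up and 0 down, or 15 and 0 adjusted over the list alone). Its calls were the epithelial cytokine Il17c (3.40 ± 0.81), Il6 (2.75 ± 0.75), Il17f (2.42 ± 0.66) and Zc3h12a (1.55 ± 0.44) in the authors' deposited table. Il17a stood at 2.80 ± 1.10 (adjusted p = 0.176) and Il22 at 3.19 ± 1.26 (adjusted p = 0.179), both uncalled in the authors' deposited table. Neutrophil genes were higher (23 genes, median 1.94, adjusted p = 3.22e-12, 2 up and 0 down, or 12 and 0 adjusted over the list alone). Among its members the chemoattractant receptor Fpr2 (2.82) and Cd177 (2.69) were called and S100a8 (2.88) and S100a9 (2.30) were not in the authors' deposited table. Neutrophil-attracting chemokines were higher as a list with no call over all genes (11 genes, median 2.27, adjusted p = 1.87e-06, 0 up and 0 down, or 9 and 0 adjusted over the list alone).

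Defence and barrier programs were higher in infected CCL28KO tongues. Complement and acute-phase genes were higher (23 genes, median 0.77, adjusted p = 2.23e-04, 1 up and 0 down, or 4 and 0 adjusted over the list alone). Their call was Saa1 (2.98 ± 0.82) in the authors' deposited table. Stress keratins and barrier-alarm genes were higher (37 genes, median 0.33, adjusted p = 5.63e-10, 5 up and 0 down, or 9 and 0 adjusted over the list alone). They included Sprr2b (3.22), Krt16 (0.59), Hbegf (0.81), Lce3d (0.48) and Serpinb2 (0.46) in the authors' deposited table, the last chosen after its value was seen. Interferon-gamma-stimulated genes were higher (23 genes, median 0.42, adjusted p = 1.52e-05, 0 up and 0 down, or 1 and 0 adjusted over the list alone) without a call. Antimicrobial genes were higher (28 genes, median 0.33, adjusted p = 3.55e-04, or adjusted p = 0.0709 at preset 0.1, 1 up and 0 down, or 4 and 0 adjusted over the list alone). Their median was 0.21 after centring by exon length (standard error 0.23 before and after), with adjusted p = 0.0133. Of these Slpi (0.42 ± 0.11) was called in the authors' deposited table. The immediate-early list was higher (20 genes, median 0.23, adjusted p = 4.47e-06, 3 up and 0 down, or 7 and 0 adjusted over the list alone). Salivary genes were higher (27 genes, median 0.40, adjusted p = 0.00106, or adjusted p = 0.0809 at preset 0.1, 2 up and 0 down, or 5 and 0 adjusted over the list alone). Calls of the first were Egr1 (0.95), Ier3 (0.81) and Junb (0.50) and of the second Lpo (2.05) and Bpifa2 (0.71) in the authors' deposited table. Oxidative phosphorylation genes were higher (29 genes, median 0.08, adjusted p = 9.69e-07, 3 up and 0 down, or 4 and 0 adjusted over the list alone). After centring by exon length their median was 0.04 (standard error 0.02 across members, 0.03 before) with adjusted p = 0.00341. The calls were Cox8b (0.60), Ndufa2 (0.61) and Ndufa1 (0.46) in the authors' deposited table. Fast muscle genes were higher here too (25 genes, median 0.14, adjusted p = 1.15e-05, 1 up and 0 down, or 1 and 0 adjusted over the list alone). Slow muscle genes were lower (10 genes, median -0.20, adjusted p = 0.0140, or adjusted p = 0.0860 at preset 0.1, 0 up and 1 down, or 0 and 3 adjusted over the list alone). Actn3 at 0.87 and Tnni1 at -0.97 were called in the authors' deposited table. IL-1 family genes with Il1a called, type I interferon, adipocyte and glucocorticoid-response genes passed upward but not at a preset correlation of 0.1, where their adjusted p lay between 0.0717 and 0.173.

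Fibroblast and matrix genes were lower in infected CCL28KO tongues (23 genes, median -0.29, adjusted p = 1.04e-08, 0 up and 2 down, or 0 and 14 adjusted over the list alone). The collagen-binding Lum (-0.76 ± 0.18) and the matricellular Postn (-0.87 ± 0.21) were called in the authors' deposited table. Mast-cell, eosinophil and type 2 genes were lower (22 genes, median -0.33, adjusted p = 0.00106, or adjusted p = 0.0717 at preset 0.1, 0 up and 2 down, or 0 and 4 adjusted over the list alone). The mast-cell proteases Cpa3 (-0.83 ± 0.20) and Cma1 (-0.84 ± 0.21) were called in the authors' deposited table. Cell-cycle genes were lower (28 genes, median -0.45, adjusted p = 5.41e-05, 0 up and 1 down, or 0 and 1 adjusted over the list alone). Their call was Nusap1 (-0.81 ± 0.23) in the authors' deposited table. The fungal-sensing list was higher (22 genes, median 0.21, adjusted p = 0.0200, or adjusted p = 0.195 at preset 0.1, 2 up and 1 down, or 3 and 1 adjusted over the list alone). Within it the mannose receptor gene Mrc1 (-0.60 ± 0.13) was lower while Epha2 (0.52) and Hbegf were higher in the authors' deposited table. After centring by exon length calls ended for Slpi (0.42 to 0.33 ± 0.11), Lce3d (0.48 to 0.32 ± 0.14), Bpifa2 (0.71 to 0.67 ± 0.21), Junb (0.50 to 0.48 ± 0.15), Ndufa2 (0.61 to 0.46 ± 0.16), Ndufa1 (0.46 to 0.30 ± 0.13) and Serpinb2 (0.46 to 0.44 ± 0.13), from the authors' deposited table to the centred value. Each moved toward 0, and each centred p lay above the largest called before. Adjusted over all genes, Lce3d, Bpifa2, Junb, Serpinb2 and Tnni1 were not called, at an adjusted p between 0.0521 and 0.0593.

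The genotype effects of sham and infected tongues shared individual genes more than a general pattern. Across 14951 genes the effects correlated at a Pearson r of 0.194 and a Spearman rho of 0.113, and genes are not independent replicates. Still, 28 genes were higher in both tables where 0.572 would be shared by independent lists, 23 were lower in both against 0.279, and 0 went in opposite directions. Calls in sham tongues lay in runs along chromosomes. The first 10 Mb of chromosome 11 held 15 of the 92 genes tested there as calls, against 0.565 by its share of genes, and the last stretch of chromosome 7 held 9 against 0.694. Chromosome 4 between 100 and 120 Mb held 9 more, among them Tceanc2, Wdr65 and Hyi (0.92) in the authors' deposited table. Within these stretches the authors' deposited table gave falls of 8430429K09Rik (-2.79), Cabp7 (-1.24) and Tnfrsf23 (-6.35) beside rises of Rhbdd3 (0.64), Drg1 (0.33) and Mtg1 (0.67), all chosen after their values were seen. Within 20 Mb of Ccl28 only Gm7120 was called among the other genes, at -0.65 ± 0.18 (adjusted p = 0.0448) in the authors' deposited table, also chosen after its value was seen, with adjusted p = 0.0506 over all genes. It lies close to Ccl28, starting at base 119488039 of chromosome 13 where Ccl28 starts at 119623819.

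**Figure D4:**
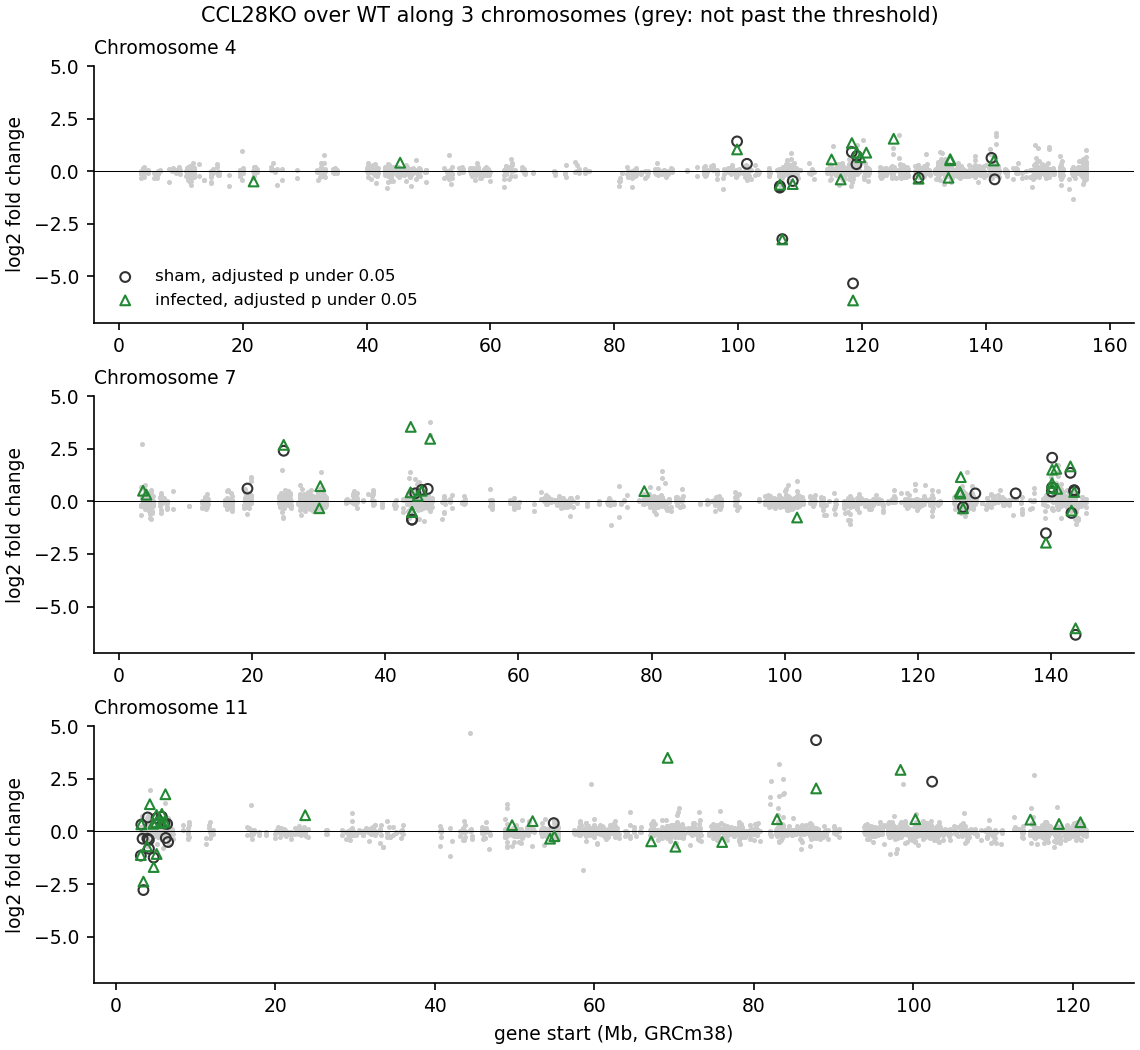
Log2 fold change of CCL28KO over WT (y axis) against gene start in Mb of GRCm38 (x axis) on chromosomes 4, 7 and 11, with circles for calls in sham tongues, triangles for calls in infected tongues and grey points for tested genes without a call. Calls of both kinds gather in the first 10 Mb of chromosome 11.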

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

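The tests of exon length, muscle share, mature neutrophil genes, chromosome segments and pairs of neighbouring calls were chosen only after the result was seen, while the test near Ccl28 was written earlier. The test of marrow and bone genes was written before its own result, but after the granule genes had been noticed in the data.

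The infection effect differed between genotypes, by a test of the difference itself, for 8 genes. The differences, CCL28KO minus WT in log2 units, were 1.17 for Icam1, 1.05 for Atp5k, 0.99 for Ier3, 0.84 for Rps29, 0.74 for Rpl38, 0.70 for Cox8b, 0.70 for Rps28 and 0.67 for Lce3a. None of the 8 stayed called with the statistic divided by its robust SD or after centring by exon length, where their adjusted p was 0.0848 or more. Of the lists that passed, 10 had a median difference above 0, at 1.63 for the IL-17 axis, 0.75 for neutrophil genes, 0.51 for glucocorticoid-response genes, 0.50 for interferon-gamma-stimulated genes, 0.50 for complement and acute-phase genes, 0.30 for stress keratins, 0.28 for antimicrobial genes, 0.22 for immediate-early genes, 0.15 for oxidative phosphorylation genes and 0.11 for endothelial genes. At a preset correlation of 0.1 the neutrophil (adjusted p = 0.0543), antimicrobial (adjusted p = 0.156), immediate-early (adjusted p = 0.0543) and endothelial (adjusted p = 0.151) lists did not pass, and the antimicrobial list did not after centring by exon length (adjusted p = 0.148, median 0.16). For oxidative phosphorylation and immediate-early genes the median infection effects were below 0 in both genotypes and nearer 0 in CCL28KO (-0.03 against -0.18 in WT, and -0.05 against -0.15). The lists that passed with a median difference below 0 were cell-cycle genes at -0.56 and mast-cell, eosinophil and type 2 genes at -0.39. Other splits of the samples were not tested, because values per library were not analysed.

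Oxidative phosphorylation genes fell as a list in WT after infection, and 46 of 82 ribosomal protein genes, which were not tested as a list, were called lower. If exon length were the whole cause, the fall would vanish after centring by length. Of the 19 oxidative phosphorylation genes called lower, 14 were still called after centring. The list median went from -0.18 to -0.13, with a standard error of 0.03 across members. This cannot decide the question, because the length used joins all annotated exons of a gene and can exceed that of its expressed transcript. The list's median length so measured was 2239 bases, while genes under 1000 bases had a median change of -0.17 in WT. Of the ribosomal genes 26 were still called after centring, at a median of -0.11 against -0.18 before. The fast muscle median was -0.00734 (standard error 0.03) where the oxidative phosphorylation median was -0.18, which argues against a smaller share of fast muscle as the whole cause. Most called members of the fast list were lower, however, and slow muscle genes were not used in this test. A response to infection was not tested and stays a hypothesis.

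Granule genes made by immature neutrophils were higher in CCL28KO sham tongues, with a median of 3.99 over 6 genes chosen for the pattern. Marrow or bone tissue in some of these libraries is a candidate source, because other marrow precursor genes and bone genes written down before the test were also shifted upward, with a larger cameraPR p of 0.0131 over both lists. The support is weak for bone, whose 19 genes had a median of only 0.09, against 1.02 for 18 marrow precursor genes, and none of either list was called over all genes. Arrival of mature neutrophils stays open, because the list of 13 mature neutrophil genes (median 0.30, standard error 0.17) leaves out S100a8, Retnlg and Cd177, which were called higher. Which libraries carry the signal was not analysed. For infection in WT the 6 granule genes had a median of 1.59 and 5 bone genes noticed in the data 2.03. None was called, but only 1 granule gene and 0 bone genes had an adjusted p. The marrow precursor and other bone genes were at -0.11 and 0.03 there. Tooth enamel genes, 4 in number, had medians of 3.64 for genotype in sham tongues and 5.49 for infection in WT. Whether WT infected libraries also held such tissue was not tested.

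Genotype calls lay in runs along chromosomes, and segments of another strain carried along with the knockout may account for them, since windows rich in sham calls also held more calls after infection among genes not called in sham, with an odds ratio of 3.42 (95% interval 1.77 to 6.09, Fisher's exact p = 2.51e-04), where infection in WT had an odds ratio of 0.986 (Fisher's exact p = 1), but infection in CCL28KO had 2.06 (Fisher's exact p = 0.0103). Each infection table shares sham libraries with the table that chose the windows, so neither is an independent control and the segments stay open. An effect of CCL28 loss spread over the genome would not by itself place calls together, and 0 of 10000 random gene sets reached the 86 pairs of sham calls within 1 Mb (highest 35), which argues against it as the whole cause. Infection calls also lay closer together than random sets, at 1.42 times the mean random count of pairs in WT and 1.51 in CCL28KO against 8.82 for sham calls, but subsets of 105 infection calls held at most 44 pairs in WT and 38 in CCL28KO. Near Ccl28 itself the odds ratio was 1.83 (95% interval 0.0453 to 10.7, Fisher's exact p = 0.426), which met the bound set in advance, an interval that includes 1, but the bound was wrong, because 1 call among 90 genes leaves an interval wide enough to hold a strong excess, and a passenger segment there cannot be told apart from none.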

How the results depend on the processing

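Centring by exon length was chosen only after the result was seen, and the other alternatives were planned.

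Over 507 results for named genes and 3526 settings, 3289 kept direction and side of the threshold, 226 lost the call, 6 gained it and 5 reversed. The 3289 include the path through the other 3 comparisons, which had no adjusted p and was judged by a difference under 1 standard error. Its outcome was nearly fixed in advance, because both paths give the same sum of changes. Results uncalled at first also had to stay so at an adjusted p under 0.01 and at a change of at least 1 log2 unit. The same held when the statistic was divided by its robust SD, so the 3289 overstate how stable the results are. Other values without an adjusted p were judged on direction alone. Of 120 settings for 28 counts and correlations, 91 stayed within 1.5 times the count or within the spread. Centring on the median moved no count beyond that.

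At an adjusted p under 0.01, infection in WT gave 384 genes higher and 775 lower, infection in CCL28KO 186 and 35, and genotype in infected tongues 51 and 40. With a change of at least 1 log2 unit also asked for, the counts were 75 and 12 for infection in WT, 192 and 13 for infection in CCL28KO, 18 and 13 for genotype in sham tongues, and 33 and 19 for genotype in infected tongues. Stricter thresholds lower these counts by construction. Centring by exon length gave 486 genes higher in WT, 409 of them among the 844 called before, and the cause was not tested beyond the trend it removed.

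For the difference of infection effects, 0 genes were higher with the statistic divided by its robust SD and 0 after centring by length, where 1250 had an unadjusted p under 0.05 by the Wald test. The path through the genotype tables gave 1 gene lower and an adjusted p under 0.1 gave 2 lower, and the cause was not tested. With a preset correlation of 0.1, the lists lower in CCL28KO after infection numbered 2, those higher and lower by genotype in sham tongues 3 and 2, those by genotype in infected tongues 9 and 2, and those higher in the difference 6. A larger preset correlation widens each test by construction. With cameraPR on ranks of the Wald score, the antimicrobial (adjusted p = 0.162), fibroblast (adjusted p = 0.0922) and hypoxia (adjusted p = 0.171) lists did not pass for infection in WT. On ranks, dendritic-cell genes did not pass for infection in CCL28KO (adjusted p = 0.0727). Nor did slow muscle genes by genotype in infected tongues (adjusted p = 0.105) or endothelial genes in the difference (adjusted p = 0.0532). With cameraPR on genes with a mean of at least 10, dendritic-cell (adjusted p = 0.132) and B-cell genes (adjusted p = 0.181) did not pass for infection in CCL28KO. Nor did type I interferon genes for infection in WT (adjusted p = 0.0746) or adipocyte genes by genotype in infected tongues (adjusted p = 0.0742). No list that passed turned direction.

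For genes with a mean of at least 100, infection effects correlated at 0.609 (Pearson) and 0.396 (Spearman) and genotype effects at 0.265 (Pearson), with 14 genes lower in both genotype tables. The cause was not tested.

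The reversals were all of uncalled values near 0. After centring by length Krt13 in WT was at 0.00565, Nnt in WT at -0.0688, Ccr10 in CCL28KO at 0.0343 and Ier3 in WT at 0.0670, and centring on the median put Nnt in WT at -0.00837. The cause was not tested.

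No paired analysis was possible because values per library were not analysed, which also left out dropping each replicate in turn, a replicate block and splits of the samples. Il17a and Il17f in WT had no adjusted p from the authors, where genes with means up to 14.2 lacked one, against 2.73 for infection in CCL28KO.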

Other observations

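The test of sex was written before its result was seen, and the tooth and marrow lists were chosen only after the result was seen.

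Tooth enamel matrix genes, 4 in number, did not follow the response to infection. Their median was 5.49 for infection in WT, -4.34 for infection in CCL28KO, 3.64 for genotype in sham tongues and -6.02 for genotype in infected tongues. None was called, but only 1 had an adjusted p, for genotype in sham tongues, so the others could not be called. In the difference of infection effects 2 were measured, at a median of -12.6, with 0 called over all genes and 2 lower adjusted over the list alone. Bone genes noticed in the tables, 5 in number, had medians of 2.03, -3.01, 5.27 and -0.72 in the same order. The granule genes were lower after infection in CCL28KO at a median of -2.72, with Mpo (-2.72) called in the authors' deposited table, and Ibsp (-3.34) and Bglap (-2.93) among bone genes, all chosen after their values were seen.

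Mature neutrophil genes, 13 measured, had a median of 2.68 for infection in WT, 4.05 in CCL28KO and 1.91 for genotype in infected tongues. Of genes called in both genotype tables with a known place, 49 had the same sign, and 21 of them (42.9%) lay in the windows rich in sham calls.

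Xist, the transcript of the inactive X chromosome, changed by at most 0.30 log2 units in any of the 4 tables, which argues against groups of unlike sex. It was called only for infection in WT, at 0.30 ± 0.09 (adjusted p = 0.00732) in the authors' deposited table. The test used Xist alone, although 1 other marker gene of sex was measured.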
